A study of Rattus norvegicus with 12 samples.

How the data were processed

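Rat calvarial bone was profiled 6 h after surgery on 12 one-colour Agilent arrays labelled with Cy3, 4 each from laser-ablated, bur-drilled and control bone of animals 10 weeks old. Per the labels, the defect measured 8 by 3 mm, 200 ng of total RNA was labelled, and the laser was passed in 3 strokes at 127 mJ per pulse and 20 Hz. Samples were grouped by their titles. Each array file holds the spot intensity values that the authors deposited, made with Agilent Feature Extraction 11.0.1.1 per the file headers and the submitters' processing notes, with background already subtracted in the processed signal. The authors also deposited a table of log2 quantile-normalized values and tables of their comparisons with a log2 fold change, a p-value and an adjusted p-value per probe, whose columns have the form that limma writes. Their model is not given in the sources used here.

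The processed signal of 62976 spots per array was log2 transformed, control spots and spots with an outlier mark were left out, and the spots of a probe were averaged, giving 45598 probes. Each array's 75th percentile was subtracted. Probes were kept when well above background on at least 4 of the 12 arrays, whatever the group, which left 30134. For each gene name the probe with the highest mean was used, giving 22990 genes. Names came from a RefSeq table of the GRCr8 assembly by accession for 21184 probes (46.5%), and other probes kept the name in the files, which can be old. Of 5430 genes with several probes kept, 269 in the laser and 295 in the bur comparison with control had probes passing in both directions. Coordinates are those of the array design, on RGSCv3.4. Scaling on the 75th percentile fixes the level of each array, so a change shared by most genes is not visible, and the share of higher against lower calls depends on the scaling.

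Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 arrays in one fit with a mean per group), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors are limma's moderated ones for genes and come from the array means for lists. Where a probe was well above background on 0 arrays of a group, the difference is given as a bound, at least N-fold: the mean of the brighter group against the mean, in the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background on that array. Such bounds hold for the main processing only, and normexp with its offset gives smaller differences for dim probes. They allow for background only and not for the spread between arrays. The 32 gene lists, holding 448 symbols of which 421 were measured, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. With an estimated correlation 0 lists passed in any comparison, while fry, which asks only whether a list moves on balance one way, passed 19, 21 and 0. Exact permutation tests of Sost used all 70 assignments of 8 arrays.

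The designs, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Sost, the 10 largest rises and 10 largest falls among genes with an official symbol that passed and whose groups did not overlap, and from each list up to 3 members with the smallest adjusted p, or for a list with none the member with the smallest p. Where this gave over 30 genes, fewer were named from each list, in that order. A few genes that the rule picked are not reported here and were left out of the search for arrays set apart, while counts of genes and lists include them.

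Alternatives covered quantile normalization, a percentile over probes well above background on all arrays, normexp background correction with offset 50, the authors' deposited table, other filters, other treatment of several probes, only 2 groups in the fit, replicate number or slide as a block, an intensity trend, array weights, a minimum log2 fold change of 1, and leaving out each array. Slide was a fixed block for laser against bur, where slides held both groups, and a random block for the comparisons with control. The block for laser against bur was first run on the 8 treated arrays only and then on all 12 as the design states. The first form was added to the alternatives, and gene counts of both are given. Median centring, the use of 1 treated slide at a time and, for named genes or lists, the mean of a gene's probes, an intensity trend and array weights were also added after seeing the data.

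The scripts were tested on simulated data with 200 changed genes among 22990. For laser against bur, 92% of 4-fold, 46% of 2-fold and 8% of 1.5-fold changes were recovered. For laser against control the shares were 74%, 30% and 6%, and for bur against control 86%, 52% and 18%. All 3 comparisons were simulated from the same means and spreads, with 50 genes for each fold. Differences between these shares thus reflect the draw, as does the 88% of 8-fold changes recovered for laser against bur. They are not sensitivities of each comparison. Far more genes than 200 passed against control, so the simulations do not resemble those comparisons.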

Results

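RNA of rat calvarial bone, the flat bone of the skull vault, was measured 6 h after surgery on 12 one-colour arrays, 4 for each of 3 groups. In the laser group a rectangular defect was ablated with an Er:YAG laser, an infrared laser whose light is strongly absorbed by water. In the bur group a defect of the same size was drilled with a rotating bur. In the control group the periosteum was lifted and the bone was left uncut. Between 67.8% and 73.7% of the non-control spots of an array were well above background, the 75th percentile signal ranged from 197.2 to 383.2, and 0 spots were saturated. After the filter on dim probes 22990 genes remained. The number of arrays limits the precision of every value, and the labels do not say that the 4 samples of a group came from separate animals, so p-values measure the spread between these samples. The 4 control arrays lay on 1 slide and the 8 treated arrays on 2 others, each with 2 laser and 2 bur arrays. Spike-in control spots were brighter on treated than on control arrays by 3.21 on the log2 scale of raw signal. In every comparison with control, treatment thus cannot be told apart from slide, scan or a difference in how the arrays were prepared.

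The comparison of laser-ablated with control bone asks what changed in bone within 6 h of ablation. Lists of genes of bone-forming cells rose, and lists of proliferating cells and of most marrow and blood cell types fell, in camera at the preset correlation. None of them passed with a correlation estimated from the data (adjusted p = 0.513), and monocyte and macrophage markers did not pass in either. Signals are relative to the level of each array. Neither the rises nor the falls of these lists can therefore be told apart from a changed share of cell types in the samples. Of the 10 measured osteocyte genes, 9 rose and 1 fell, and the 1 that fell was Sost, which encodes sclerostin, an inhibitor of Wnt signalling secreted by osteocytes. Of the 18 measured cell cycle genes all 18 fell. Altogether 11445 genes changed, 7403 higher and 4042 lower, by limma with Benjamini-Hochberg adjustment.

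Osteocyte genes shifted by a mean log2 fold change of 1.56 (SE 0.18 from 4 arrays per group), with 9 higher and 1 lower over all genes and likewise when adjusted over the list alone. Their camera test passed (adjusted p = 0.000566), but not with the correlation taken from the data (adjusted p = 0.513 with an estimated correlation). Dmp1, a phosphoprotein of mineralising bone matrix, rose by 2.88 on the log2 scale (SE 0.25, adjusted p = 7.69e-05), a 7.36-fold difference. Slc13a5, a citrate transporter, rose by 2.36 (SE 0.26) and Mepe, a matrix glycoprotein of osteocytes, by 1.63 (SE 0.19). Of the 15 osteoblast and bone matrix genes 14 rose and 1 did not pass, the same count as when adjusted over the list alone (mean 1.34, camera adjusted p = 4.35e-05, adjusted p = 0.513 with an estimated correlation). Among them were Omd, a keratan sulphate proteoglycan of bone, 6.36-fold higher, Runx2, the transcription factor of osteoblast commitment, 4.53-fold higher, and Alpl, tissue-nonspecific alkaline phosphatase, 3.32-fold higher by the probe used, while a further Alpl probe did not pass (log2 0.23, SE 0.28). Sost fell by 0.80 on the log2 scale (SE 0.30, adjusted p = 0.0460), and its 2-sided exact permutation test gave p = 0.0571 where 0.0286 is the smallest possible. Its call was kept in 4 of 12 fits without 1 array and in 11 of 16 other settings.

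Heat shock genes rose as a list, 10 of 14 higher and 0 lower, also 10 when adjusted over the list alone (mean 1.13, SE 0.12, camera adjusted p = 0.00658, adjusted p = 0.513 with an estimated correlation). Hspa1a, the stress-inducible Hsp70 chaperone, was 25.8-fold higher (log2 4.69, SE 0.39), Cryab, a small heat shock protein, 4.32-fold, and Hspa8, the constitutive Hsp70, 1.92-fold by the probe used. Of the 4 Hspa8 probes 3 passed and 1 did not (log2 0.04, SE 0.12). Immediate early genes, which answer a stimulus without new protein synthesis, had 11 of 21 members higher and 1 lower, also 11 and 1 when adjusted over the list alone (mean 0.90, camera adjusted p = 0.0127, adjusted p = 0.513 with an estimated correlation). The zinc finger factors Klf4 and Egr1 rose 2.90-fold and 3.79-fold.

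The cell cycle list fell by 1.84 on average (SE 0.44), with 18 of 18 members lower, also when adjusted over the list alone (camera adjusted p = 3.61e-07, adjusted p = 0.513 with an estimated correlation). Mcm6, a subunit of the replicative helicase, was 4.80-fold lower, Aurkb, a mitotic kinase, 6.19-fold, and Top2a, a DNA topoisomerase, 8.02-fold. Erythroid markers fell as a list (mean -2.60, SE 0.94), with 10 of 12 lower and 11 when adjusted over the list alone, among them Ermap, 3.31-fold lower, and the erythroid transcription factor Klf1, 6.26-fold (3.71-fold without laser replicate 1). Granulocyte precursor markers fell by 1.96 (SE 0.45), 8 of 9 lower and also 8 when adjusted over the list alone, with Ngp 6.56-fold and myeloperoxidase, Mpo, 5.14-fold lower. Platelet and megakaryocyte markers fell by 2.00 (SE 0.53), 8 of 9 lower and also 8 when adjusted over the list alone, with Itga2b, an integrin of platelets, 6.34-fold lower and Gp1ba 3.29-fold lower, well above background on 1 of 4 laser arrays. The camera adjusted p of these 3 lists was 0.000147, 0.000256 and 0.000404, and each had adjusted p = 0.513 with an estimated correlation. One array, laser replicate 1, was the lowest laser array on these 3 lists and lay apart for erythroid markers. Its mean erythroid signal was -1.05 on the log2 scale against 2.28 to 2.85 on the other 3 laser arrays, and without it the erythroid mean was -1.68.

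Mature neutrophil markers had 6 of 11 members lower (7 when adjusted over the list alone, mean -1.07, camera adjusted p = 0.000869), with the collagenase Mmp8 4.32-fold and Cd177 5.35-fold lower. B cell markers had 8 of 11 lower, also 8 when adjusted over the list alone (mean -1.47, camera adjusted p = 0.00138), with Cd22 4.41-fold lower. T and NK cell markers had 7 of 11 lower, also 7 when adjusted over the list alone (mean -1.05, camera adjusted p = 0.00523), and Cd5, not well above background on the laser arrays, was at least 3.84-fold lower. Adipocyte markers had 5 of 6 lower (6 when adjusted over the list alone, mean -2.11, camera adjusted p = 0.00211), with the lipid droplet gene Cidec at least 4.89-fold and resistin, Retn, 3.41-fold lower. These 4 lists had adjusted p = 0.513 with an estimated correlation. Monocyte and macrophage markers did not pass (7 of 16 lower, 2 higher, camera adjusted p = 0.0624, and 7 and 3 when adjusted over the list alone), and Csf1r, the receptor of macrophage colony-stimulating factor, was 1.70-fold lower.

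Neural and glial markers fell by 1.42 on average (SE 0.55, camera adjusted p = 0.0262, adjusted p = 0.513 with an estimated correlation), with 3 of 11 lower, also 3 when adjusted over the list alone. The mean neural signal was -2.46 on control replicate 4, inside the laser range of -2.93 to -1.82, and -0.95 to -0.24 on the other 3 control arrays. Among the largest falls over all genes, Elavl3 was at least 10.9-fold lower (8.90-fold without control replicate 3 and 19.8-fold without control replicate 4). Nxph1 was at least 7.64-fold and Rab3b at least 6.82-fold lower (4.40-fold without control replicate 2). These are bounds, since none of the 3 genes was well above background on a laser array. Gad1, which makes GABA, fell by 5.01 on the log2 scale and was well above background on 3 of 4 laser arrays, Synpr by 4.80 (1 of 4) and the water channel gene Aqp4 by 3.98 (4 of 4) and Fabp7 by 3.90 (2 of 4). Without control replicate 4 the log2 fold changes were -5.61 for Gad1, -5.42 for Synpr and -4.54 for Fabp7. Fabp7 stood at -3.28 without laser replicate 4. Gfap, of astrocytes, was 4.57-fold lower, measured on 1 of 4 laser arrays. Lep, the gene of leptin, fell by 3.87 (1 of 4). Skeletal muscle markers had 0 of 13 members passing, also 0 when adjusted over the list alone, although their list test passed (mean -1.85, SE 1.61, camera adjusted p = 0.0244, adjusted p = 0.696 with an estimated correlation). Tnnt3 had a log2 fold change of -2.02 (adjusted p = 0.111). Without control replicate 2 or control replicate 4 the muscle list lost its call (means -0.72 and -1.22), Tnnt3 passed without control replicate 1 or 3 (-2.69 and -2.85) and stood at -1.11 without control replicate 2, the muscle mean was -2.91 without control replicate 3, and the neural list lost its call without control replicate 3 (mean -1.14). The mean muscle signal of the control arrays ranged from -2.53 to 4.03. The labels do not say whether adjoining muscle, neural or fat tissue was collected with the control bone, so the falls of these lists are not shown to be changes within bone.

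The leading rises named here are not members of the fixed osteocyte or osteoblast lists. Cyp2w1, a cytochrome P450 that was not well above background on the control arrays, was at least 17.7-fold higher (12.8-fold without laser replicate 1). The olfactory receptor Or6b13 was at least 6.20-fold higher and C4h12orf60 at least 5.18-fold in the main processing. For Eomes, a T-box factor, the probe used was at least 7.20-fold higher, but a further probe passed in the opposite direction (log2 -3.17, SE 0.61), so the direction of the gene is open. Ugt2a1 rose by 4.45 on the log2 scale (SE 0.83, and 3.68 without laser replicate 1), Amer1 by 4.20 (SE 0.50), Adam7 by 4.10 (SE 0.32), the adenosine receptor Adora3 by 4.07 (SE 0.75) and Ica1l by 3.95 (SE 0.39).

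The other 17 lists did not pass against control. Inflammatory cytokines and prostaglandin enzymes had 5 of 16 members higher and 1 lower (camera adjusted p = 0.158), with Il11 3.92-fold and the prostaglandin synthase Ptgs2 3.63-fold higher, Il11 being well above background on 3 of 4 control arrays. Matrix remodelling and plasminogen system genes had 7 of 18 higher and 1 lower (Mmp2 3.62-fold higher), Wnt target genes 6 of 10 higher and 1 lower (Ccnd1 3.27-fold higher), periosteal and fibroblast markers 6 of 11 higher and 0 lower (Fap 2.39-fold higher) and keratinocyte markers 6 of 8 higher and 1 lower (Krt10 1.89-fold higher). Growth factor and BMP pathway genes had 10 of 20 higher and 3 lower, Wnt antagonists 4 of 10 and 1, hypoxia and glycolysis genes 6 of 20 and 3, and chemokines 5 of 22 and 3. NF-kB feedback genes had 3 of 13 higher and 1 lower, oxidative stress and metallothionein genes 2 of 10 and 1, unfolded protein and integrated stress response genes 4 of 13 and 3, and housekeeping genes 2 of 10 and 2. Endothelial markers had 1 of 11 higher and 3 lower, osteoclast genes 2 of 13 and 3, p53 target and apoptosis genes 2 of 13 and 3, and interferon-stimulated genes 0 of 16 and 3. Adjusted over the list alone, the counts higher and lower were 11 and 4 for growth factor genes, 5 and 2 for chemokines, 3 and 0 for NF-kB feedback genes, 1 and 2 for endothelial markers and 0 and 1 for interferon-stimulated genes, and otherwise the same. The mean of the housekeeping, oxidative stress and unfolded protein lists changed sign under another scaling, and for these and the chemokines the sign of the mean differed from that of the camera test.

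**Figure D1:**
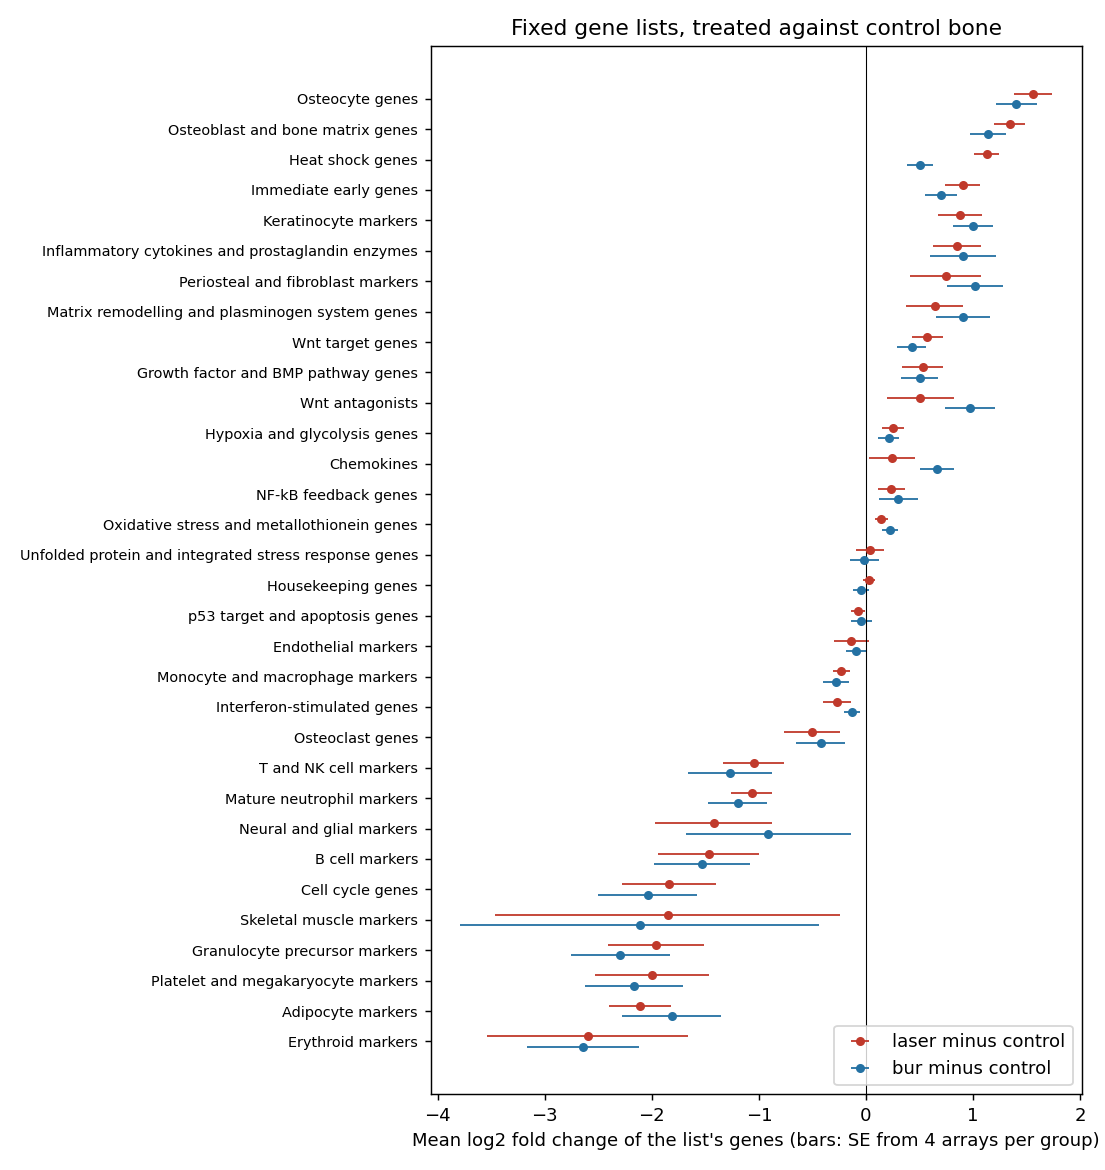
Mean log2 fold change of each fixed gene list (horizontal axis) for laser minus control and bur minus control bone, with bars showing the SE from 4 arrays per group. Osteocyte genes lie at 1.56 and 1.40 and erythroid markers at -2.60 and -2.64.

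Slide and scan cannot be told apart from treatment here, since 0 slides held both control and treated arrays, and with slide as a random block 8819 genes passed and Sost did not (adjusted p = 0.106). The median log2 fold change of all genes was 0.21, and the share of higher calls, 64.7%, was 55.3% to 58.0% under the other scalings. The median depended on signal. In 5 groups of 4598 genes, from dimmest to brightest, it was 0.56, 0.16, 0.01, 0.11 and 0.32. The brightest group held the largest share of higher calls (43.8%). A rise of a gene or list that is dim, or among the brightest, may therefore be in part a shift shared by genes of like signal. Of the genes named other than Sost, C4h12orf60 did not pass with normexp (log2 0.69), nor Hspa8 with quantile normalization (0.35), nor Eomes with the mean of its probes (0.29). With treated arrays of slide 1 only Aqp4 (-4.22), Fabp7 (-3.25) and Synpr (-4.46) did not pass, nor Cd5 with those of slide 2 only (-1.54). In limma on the authors' deposited table of normalized values Eomes did not pass (0.16, from the further probe), and the heat shock list lost its call (mean 0.79), as it did with slide 1 only (0.96). The neural and muscle lists lost theirs with quantile normalization (means -1.54 and -1.91), with the percentile over probes well above background on all arrays (-1.53 and -1.96) and with only such probes (-1.45 and -1.83), the muscle list also with slide 1 only (-1.33), and T and NK cell markers with only such probes (-1.15).

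The comparison of bur-drilled with control bone asks the same of mechanical drilling. Lists of bone-forming, proliferating and most marrow and blood cells again passed at the preset correlation, and 0 lists passed with an estimated correlation (smallest adjusted p = 0.572). The heat shock, immediate early and neural lists passed for laser only and the matrix remodelling list for bur only. Such unlike calls do not by themselves show a difference between laser and bur. As for laser, a changed share of cell types cannot be told apart. In limma, 9 of 10 osteocyte genes and 13 of 15 osteoblast genes rose, and all 18 cell cycle genes and 10 of 12 erythroid markers fell. Sost rose by 0.88 on the log2 scale (SE 0.30, n = 4 per group, adjusted p = 0.0310), a 1.84-fold difference, with a 2-sided exact permutation p = 0.0857. Its call was kept in 8 of 12 fits without 1 array and in 9 of 16 other settings, where the value ranged from 0.36 to 1.11. Altogether 11731 genes changed, 7527 higher and 4204 lower, by limma with Benjamini-Hochberg adjustment.

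Osteocyte genes shifted by a mean of 1.40 (SE 0.19), with 9 higher and 0 lower, also 9 when adjusted over the list alone (camera adjusted p = 0.000491, adjusted p = 0.572 with an estimated correlation). Fbln7, an adhesion protein, was 3.44-fold and Slc13a5 4.88-fold higher. Osteoblast and bone matrix genes shifted by 1.14 (SE 0.17), 13 of 15 higher, also 13 when adjusted over the list alone (camera adjusted p = 0.000303, adjusted p = 0.572 with an estimated correlation), with Omd 5.26-fold and Runx2 3.99-fold higher. Matrix remodelling and plasminogen system genes rose as a list, 10 of 18 higher and 12 when adjusted over the list alone (mean 0.90, SE 0.25, camera adjusted p = 0.0209, adjusted p = 0.648 with an estimated correlation). The gelatinase Mmp2 was 3.31-fold higher, the collagen cross-linking enzyme Lox 3.65-fold and the aggrecanase Adamts4 3.00-fold.

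Cell cycle genes fell by 2.04 (SE 0.46), 18 of 18 lower, also when adjusted over the list alone, with Mcm6 6.87-fold and Aurkb 7.26-fold lower. Granulocyte precursor markers fell by 2.30 (SE 0.46), 8 of 9 lower and 9 when adjusted over the list alone, with Ngp 8.52-fold and Mpo 6.78-fold lower. Erythroid markers fell by 2.64 (SE 0.52), 10 of 12 lower, also 10 when adjusted over the list alone, with Ermap 3.61-fold lower. Platelet and megakaryocyte markers fell by 2.16 (SE 0.46), 8 of 9 lower and 9 when adjusted over the list alone, with Itga2b 9.30-fold lower and Gp1ba 4.11-fold lower, measured on 1 of 4 bur arrays. The camera adjusted p of these 4 lists was 4.91e-08, 9.22e-05, 0.00012 and 0.000303, and each had adjusted p = 0.572 with an estimated correlation. Bur replicate 3 lay closest to control on several of these genes, with a mean erythroid signal of 3.10 against 0.88 to 1.34 on the other 3 bur arrays.

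Mature neutrophil markers had 5 of 11 lower (4 when adjusted over the list alone, mean -1.20, camera adjusted p = 0.000303), with Mmp8 7.61-fold and Cd177 6.53-fold lower. B cell markers had 7 of 11 lower (8 when adjusted over the list alone, mean -1.53, camera adjusted p = 0.00122), with Cd22 5.69-fold lower and the recombinase Rag1 7.02-fold lower, measured on 3 of 4 bur arrays. T and NK cell markers had 6 of 11 lower (7 when adjusted over the list alone, mean -1.27, camera adjusted p = 0.00203), with Cd5 6.25-fold lower, measured on 1 of 4 bur arrays. Adipocyte markers had 5 of 6 lower, also 5 when adjusted over the list alone (mean -1.82, camera adjusted p = 0.0048), with Retn 3.16-fold lower and Cidec 6.51-fold lower, measured on 1 of 4 bur arrays. These 4 lists had adjusted p = 0.572 with an estimated correlation. Skeletal muscle markers again had 0 of 13 members passing, also 0 when adjusted over the list alone (mean -2.11, SE 1.68, camera adjusted p = 0.0171, adjusted p = 0.648 with an estimated correlation), and Tnnc2 had a log2 fold change of -3.18 (SE 1.37, adjusted p = 0.0724), passing without control replicate 1 or 3 (-4.12 and -4.16) and standing at -2.01 without control replicate 2. The muscle list lost its call without bur replicate 4, control replicate 2 or control replicate 4 (means -1.57, -0.98 and -1.49), and its mean was -3.17 without control replicate 3.

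In the main processing Cyp2w1 was at least 15.6-fold higher than in control (10.8-fold without bur replicate 1), Or6b13 at least 5.88-fold, the vomeronasal receptor Vom2r65 at least 4.61-fold, Or10ag57 at least 4.24-fold and C4h12orf60 at least 3.80-fold, none being well above background on a control array. The Eomes probe used was at least 8.17-fold higher (6.22-fold without bur replicate 1 and 12.3-fold without bur replicate 4), while the further probe passed in the opposite direction (log2 -2.30, SE 0.61). Thsd4 rose by 3.95 on the log2 scale (SE 0.85) and Id3, an inhibitor of DNA binding, by 3.84 (SE 1.25), each measured on 1 of 4 control arrays. Id3 lost its call without bur replicate 1 or 2 or control replicate 2, 3 or 4 (log2 3.19 to 3.78). Ugt2a1 rose by 3.74 (SE 0.83) and Adora3 by 3.62 (SE 0.75), and without bur replicate 1 by 3.07 and 2.96. Trip13, a mitotic checkpoint ATPase, was at least 5.53-fold lower and the receptor Gpr158 at least 3.89-fold lower. On the log2 scale the centriole gene Stil fell by 3.89, Clca5 by 3.86, Rab3b by 3.73, Mal2 by 3.59 and Plin4, a lipid droplet protein, by 3.55, each measured on 1 of 4 bur arrays. The log2 fold change of Clca5 was -4.54 without bur replicate 3, and that of Rab3b was -3.10 without control replicate 2. Trim10, an erythroid RING protein, fell by 3.65 (SE 0.86).

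Heat shock genes did not pass as a list (6 of 14 higher and 2 lower, also when adjusted over the list alone, camera adjusted p = 0.477), with Hspa8 1.57-fold and Cryab 2.53-fold higher. Immediate early genes had 10 of 21 higher and 2 lower (camera adjusted p = 0.063), with Maff 3.21-fold higher. Il11 and Ptgs2 were 3.06-fold and 3.49-fold higher in a list that did not pass (camera adjusted p = 0.148). Neural and glial markers had 3 of 11 lower (camera adjusted p = 0.063). The 20 lists that did not pass included chemokines, with 7 of 22 higher and 2 lower (7 and 1 when adjusted over the list alone), Wnt antagonists, with 4 of 10 higher and 0 lower (also when adjusted over the list alone), and keratinocyte markers, with 6 of 8 higher and 1 lower (also when adjusted over the list alone). The mean of the housekeeping, oxidative stress, unfolded protein and endothelial lists changed sign under another scaling.

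With slide as a random block 8969 genes passed and Sost did not (adjusted p = 0.0775), and as for laser, slide and treatment cannot be told apart. The median log2 fold change was 0.23, and the 64.2% share of higher calls was 51.5% with median centring, 51.6% with normexp background correction and 54.1% in the authors' deposited table of normalized values. As for laser, the median depended on signal. In 5 groups of 4598 genes, from dimmest to brightest, it was 0.69, 0.23, 0.02, 0.11 and 0.30. With only probes well above background on all arrays the adipocyte (mean -1.33), muscle (-1.95) and T and NK cell (-1.18) lists lost their calls, and with treated arrays of slide 1 only the muscle (-1.26) and matrix remodelling (0.84) lists. Calls ended with normexp for C4h12orf60 (log2 0.44), Or6b13 (0.64), Or10ag57 (0.43) and Id3 (1.57), with quantile normalization for Hspa8 (0.21), with the mean of its probes for Eomes (0.82), and in limma on the authors' deposited table for Id3 (2.34) and, from other probes than the main ones, for Eomes (0.25) and Hspa8 (0.15). Of the 4 Hspa8 probes 3 were higher and 1 lower (log2 -0.47).

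**Figure D2:**
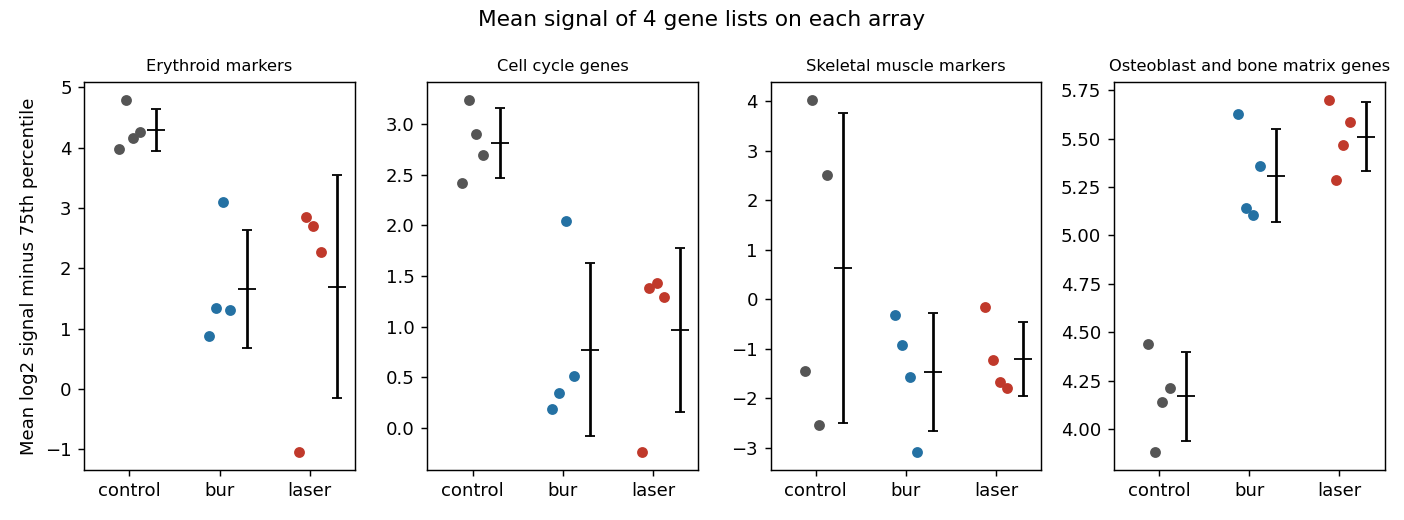
Mean log2 signal relative to the array's 75th percentile for 4 gene lists on each of the 12 arrays (points), with group mean and SD (bars). Laser replicate 1 lies at -1.05 for erythroid markers, and the 4 control arrays range from -2.53 to 4.03 for skeletal muscle markers.

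Whether the responses to laser and to bur resembled each other was examined over all 22990 genes. Genes higher against control after both treatments numbered 6368 and those lower after both 3381, and 2 genes passed in opposite directions. Independent lists would share 2424 and 739, but the comparisons share their controls. With 2 control arrays for laser and the other 2 for bur, 2074 to 2667 genes were higher and 848 to 1113 lower in both, where independent lists would share 598 to 834 and 144 to 227. Those control arrays still lay on 1 slide. The log2 fold changes correlated across genes, which are not independent replicates, at r = 0.945. Unchanged groups simulated against the shared controls gave 0.499, and controls split 2 and 2 gave 0.853. Neither value allows for a slide or scan offset of the control arrays, which both comparisons would share. The covariance was 0.977 against a simulated 0.0727, a difference of 0.904.

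**Figure D3:**
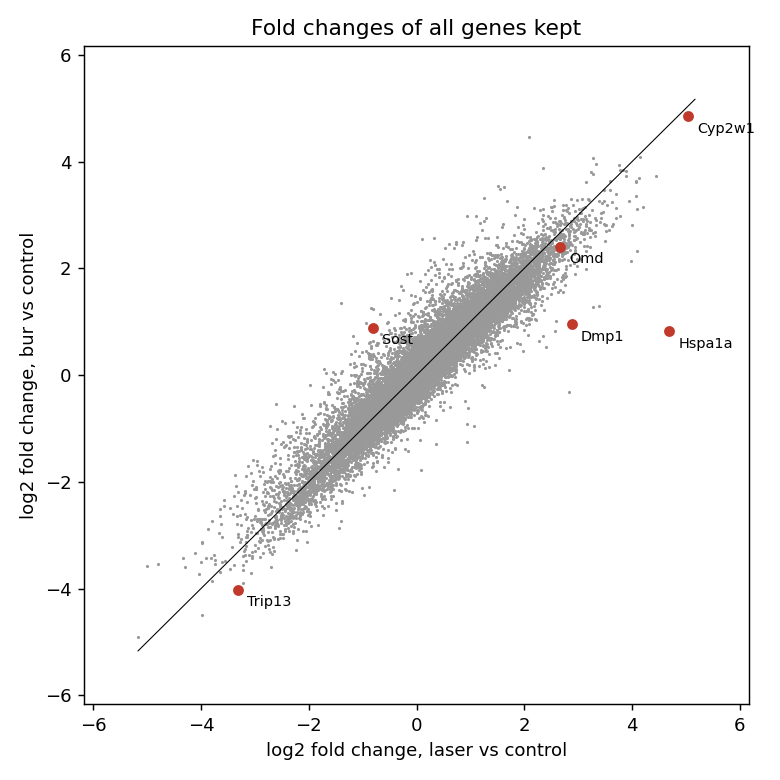
Log2 fold change of each gene after laser (horizontal axis) and after bur (vertical axis), both against control, with the line of equal values. Hspa1a lies at 4.69 after laser and 0.82 after bur, and Sost at -0.80 and 0.88.

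The comparison of laser with bur bears on the study's stated subject, the effect of Er:YAG irradiation on Sost. Hspa1a was 14.6-fold higher after laser than after bur (log2 3.87, SE 0.39, n = 4 per group, adjusted p = 0.0175) and was the only one of 22990 genes to pass in limma, while 1497 had an unadjusted p under 0.05. Sost differed by -1.68 on the log2 scale (SE 0.30), 3.21-fold, which did not pass over all genes (adjusted p = 0.249). All 4 laser arrays lay below all 4 bur arrays for Sost, and its 2-sided exact permutation p = 0.0286 is the smallest that 4 against 4 can give. Genes with no overlap between the groups were 3.58% of all genes, where chance gives 2.86%.

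The Sost probe lies on chromosome 10, positions 91026551 to 91026610 of the minus strand in the rat build RGSCv3.4 that the file headers name, and it was well above background on 12 of 12 arrays. Within the 2 slides Sost differed by -1.73 and -1.63 (SE 0.43 each), and with slide as a block by -1.68 (SE 0.29, adjusted p = 0.126). In the authors' deposited table of comparisons the Sost log2 fold change was -1.11 with adjusted p = 0.0954, and over the settings tried here its adjusted p ranged from 0.126 to 0.971. The Hspa1a probe lies on chromosome 20, positions 3958289 to 3958348. Within the slides Hspa1a differed by 3.29 and 4.45, and with slide as a block by 3.87 (SE 0.33, adjusted p = 0.00719). A further Hspa1a probe gave 3.50 (SE 0.54, adjusted p = 0.124 over all probes).

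Heat shock genes were higher after laser as a list (mean 0.62, SE 0.14, camera adjusted p = 7.57e-08, adjusted p = 0.461 with an estimated correlation), with 1 of 14 members higher over all genes and 4 when adjusted over the list alone. Those 4, named after their values were seen, were Hspa1a, Hsph1 (log2 1.57), Cryab (0.77) and Dnaja1 (0.71). Of the 14 members 13 lay above 0, but the list's median was 0.26, so its mean leans on Hspa1a (log2 3.87). The list's shift was 0.48 and 0.76 within the slides and kept its call with slide as a block (adjusted p = 6.9e-08). Chemokines were lower as a list (mean -0.42, camera adjusted p = 0.0278, adjusted p = 0.461 with an estimated correlation), with 0 of 22 members passing in limma and 1 when adjusted over the list alone, Cxcl9 (log2 -1.33, SE 0.28, measured on 2 of 4 laser arrays). Osteoblast and bone matrix genes were higher (mean 0.20, and 0.31 without bur replicate 1, camera adjusted p = 0.0418, adjusted p = 0.953 with an estimated correlation), with 0 of 15 passing in limma and 1 when adjusted over the list alone, Spp1, the gene of osteopontin (log2 1.03, SE 0.25). Interferon-stimulated genes were lower (mean -0.14, and -0.02 without laser replicate 1, camera adjusted p = 0.0418, adjusted p = 0.461 with an estimated correlation), with 0 of 16 passing, also 0 when adjusted over the list alone, and Irf1 at -0.34 (SE 0.15, and -0.18 without bur replicate 3). With slide as a block the last 3 lists lost their calls (adjusted p = 0.0572, 0.0603 and 0.0603), as they did with the percentile over probes well above background on all arrays (means -0.45, 0.18 and -0.17). Osteoblast genes also lost theirs with quantile normalization (mean 0.10), with normexp (0.19) and in the authors' deposited table of normalized values (0.11), chemokines and osteoblast genes with only probes well above background on all arrays (-0.29 and 0.20), and interferon-stimulated genes with the replicate block (-0.14). Their shifts within the 2 slides were -0.29 and -0.56 for chemokines, 0.11 and 0.29 for osteoblast genes, and -0.22 and -0.06 for interferon-stimulated genes.

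Osteocyte genes did not pass as a list (mean 0.16, camera adjusted p = 0.46), with 0 of 10 passing in limma and 1 higher and 1 lower when adjusted over the list alone, Dmp1 and Sost. Dmp1 had a log2 fold change of 1.93 (SE 0.25, adjusted p = 0.115) and Egr1 1.34 (SE 0.21, adjusted p = 0.127). The mean of 7 lists with no call changed sign under another scaling, those of endothelial, housekeeping, hypoxia, inflammatory cytokine, keratinocyte, NF-kB feedback and p53 target genes. Among lists with no call, Adamts4 stood at -0.67, Hbegf at 0.70, Ccnd1 at 0.77 and Postn, the periosteal matrix protein periostin, at -2.06 (SE 0.83). With slide as a block 10 genes passed, 9 higher and 1 lower, Dmp1 among them (adjusted p = 0.0335). When the same block was fitted on the 8 treated arrays alone, 1 gene passed, Hspa1a (adjusted p = 0.0411), and Dmp1 did not (log2 1.93, SE 0.26, adjusted p = 0.248). Dmp1 also passed with normexp (adjusted p = 0.0140) and with an intensity trend (adjusted p = 0.0396). Hspa1a did not pass when only the 2 groups compared were fitted (adjusted p = 0.144), nor with the mean of its probes (log2 3.69, adjusted p = 0.108), nor with treated arrays of 1 slide only, nor without laser replicate 3, control replicate 3 or any 1 bur replicate (adjusted p from 0.0547 to 0.121), and over all settings its adjusted p ranged from 0.00299 to 0.608.

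**Figure D4:**
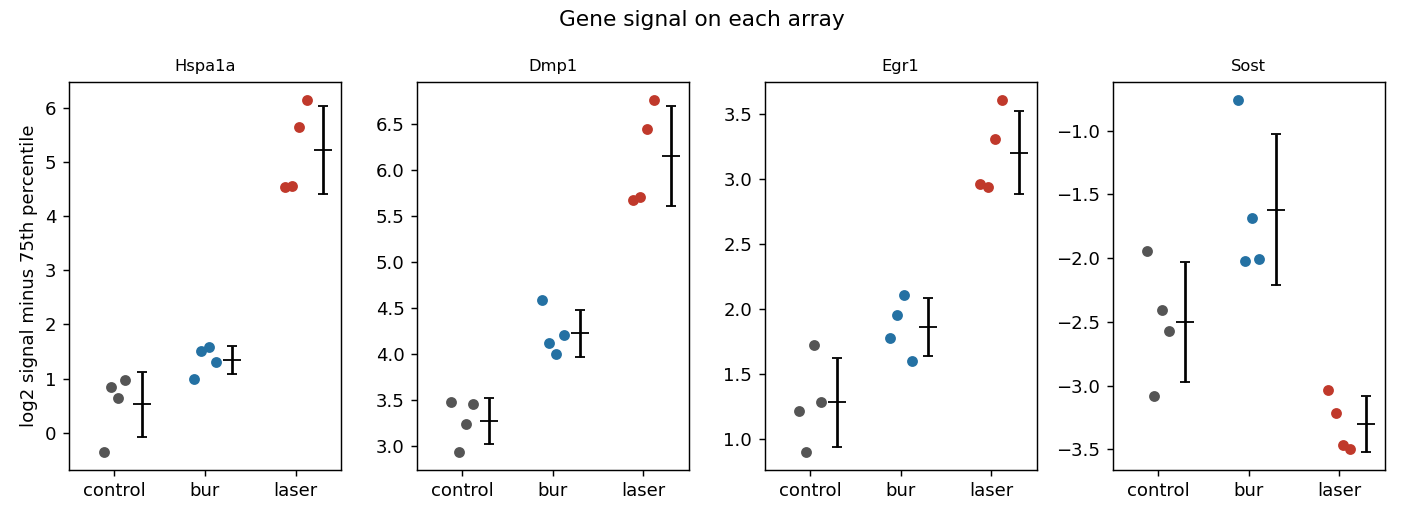
Log2 signal relative to the array's 75th percentile for Hspa1a, Dmp1, Egr1 and Sost on each of the 12 arrays (points), with group mean and SD (bars). All 4 laser arrays lie above all 4 bur arrays for the first 3 genes and below them for Sost, a mean difference of -1.68.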

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

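The tests of marrow share, of slide and scan, of slides for Sost and of osteocyte number were chosen only after the result was seen. Among 324 groups of 4 values (228 for genes named in the text and 96 for lists), 25 held an array set apart from the other 3 by Dixon's ratio, and chance marks about 1 in 20. Laser replicate 1 accounted for 9 of them and bur replicate 3 for 7.

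On the log2 scale relative to the array's 75th percentile, laser replicate 1 stood apart for erythroid markers (-1.05), B cell markers (-1.83), cell cycle genes (-0.24), Mcm6 (-2.23), Top2a (-2.14), Klf1 (-2.83), Cd22 (2.27) and Trim10 (-5.04), all low, and Ica1l (3.23), high. Bur replicate 3 stood apart on the high side for B cell markers (0.61), Mcm6 (-0.85), Aurkb (-2.03), Top2a (0.88), Klf1 (0.77), Gp1ba (-4.58) and Trim10 (-0.84). Control replicate 2 was high for Ermap (-0.057) and low for matrix remodelling and plasminogen system genes (0.49). Control replicate 1 was high for C4h12orf60 (-5.48) and control replicate 4 low for Elavl3 (-4.51). Laser replicate 2 was low for Ccnd1 (1.58) and Fap (3.19), laser replicate 4 for Plin4 (-6.67) and bur replicate 2 for Plin4 (-6.74), and bur replicate 4 was high for Hspa8 (8.66). The 350 spike-in control spots, which no comparison uses, were brighter on treated than on control arrays by 3.21 on the log2 scale of raw signal (8.37, SD 0.22, against 5.16, SD 0.18). The labels do not say whether control arrays were labelled and hybridised together with the treated ones. Any such difference falls together with slide and scan, and with treatment, in every comparison with control, the 11445 and 11731 genes included.

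The gene counts against control exceeded those of other splits. For laser 1 of the 35 splits of the 8 arrays, the real one, gave as many as 11445 genes (highest other 1). For bur 1 of the 35 splits gave as many as 11731 (highest other 89). Chance is thus unlikely for both, though 1 of 35 is the smallest share this test can give. Slide and scan stay open, since the real split also parts the slide of the control arrays from the others. The counts of lists were not set apart. For laser, 11 of the 35 splits gave at least the 14 lists (highest other 16). For bur, 16 of the 35 splits gave at least the 12 (highest other 20). Most of these other splits held 3 of the 4 treated arrays on one side, and so kept part of the real contrast. Chance is therefore not excluded for the number of lists, and this test can hardly exclude it. For laser against bur, 8 of the 35 splits gave at least 1 gene. The split that follows the slides gave 1877 genes, a structure of the arrays that the blocked and within-slide values take into account. A further split, which mixed the slides and had 1 laser array on one side, gave 734 genes. It set laser replicate 1 and bur replicates 1, 2 and 4 against the other treated arrays. Mean erythroid signals were -1.05 to 1.34 on the first side and 2.28 to 3.10 on the other. The platelet, granulocyte precursor, B cell and cell cycle lists also parted along it with no overlap. The treated samples thus differed among themselves in marrow and cell cycle lists. The slide block does not take that structure into account. For the lists of this comparison, 27 of the 35 splits gave at least 4 (highest other 15). In 2 of the 35 splits the camera p of the heat shock list was as small as 2.37e-09 (the other 4.04e-10). That other split held 3 of the 4 laser arrays on one side, and so kept part of the real contrast. Chance is not excluded for these lists either, though the splits and their fits do not take the shared slides into account.

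Most marrow and blood lists were lower in treated bone than in control at the preset correlation. None passed with an estimated correlation (adjusted p of 0.513 for laser and 0.572 for bur at best), and monocyte and macrophage markers did not pass in either. A smaller share of marrow cells as the only cause would lower its cell lines alike, but erythroid markers fell further than B cell markers by 1.13 (SE 0.52) after laser and by 1.11 (SE 0.21) after bur, which for laser is only just beyond 2 SE. This pair was taken as the largest difference among 4 marrow lists, and 2 SE makes no allowance for that choice, so the laser value is weak evidence. The laser value leans on laser replicate 1, without which the mean changes were -1.68 and -1.04, while platelet minus B cell markers was -0.53 (SE 0.18). Among the treated arrays each of the 4 marrow lists was lowest on laser replicate 1 and highest on bur replicate 3. Such movement together is what a share of marrow that varied between samples would give. Mature neutrophil markers and T and NK cell markers were lowest on bur arrays instead. Markers near background could compress a fall, so a smaller share of marrow with unequal losses stays open, as does a response to surgery, and slide and scan cannot be told apart from treatment, since 0 slides held both.

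Heat shock genes were higher as a list at the preset correlation, and Sost was lower, after laser than after bur. The list did not pass with an estimated correlation (adjusted p = 0.461), 1 of its 14 members passed, and Sost did not pass over all genes (adjusted p = 0.249). The values argue against a difference between the slides, since Sost was lower within each slide (-1.63, SE 0.43, in the smaller case). Against fewer osteocytes in the laser samples as the only cause stands that the other 9 osteocyte genes averaged 0.36. The SE of that mean, 0.22, is taken over genes, so it does not measure the spread between samples. Dmp1 was the highest of these genes (1.93) and Fbln7 the lowest (-0.44). Fewer osteocytes together with a rise of such genes in the remaining cells would not show in this mean and is not excluded. The whole list, Sost included, had a mean of 0.16 (SE 0.19 from the arrays). Against noise of a dim probe stands that 0.2% of the 1000 genes nearest to Sost in mean signal differed by as much. A response of osteocytes to the way bone was cut may remain as a hypothesis, found and tested on the same arrays.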

How the results depend on the processing

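Median centring, the use of 1 treated slide at a time, the slide block on 2 groups, the overlap of genes with the controls split and, for named genes and lists, the mean of a gene's probes, and for named genes an intensity trend and array weights, were chosen after seeing the data. No gene named and no list past the threshold changed direction in any setting in which it was fitted. With only probes well above background on all arrays, 35 of 53 genes named for laser and 24 of 45 for bur could be fitted, and lists were not fitted with an intensity trend or array weights. Single probes of Eomes and Hspa8 did go both ways. The mean of a list without a call changed sign under another scaling for 3 lists for laser against control, 4 for bur against control and 7 for laser against bur. The counts of genes against control stayed within 1.5 times except with a minimum log2 fold change of 1 (5911 for laser, 5934 for bur). Genes passing for laser against bur numbered 5 with normexp, 2 with an intensity trend, 10 with slide as a block on 12 arrays and 1 with slide as a block on the 8 treated arrays. They numbered 0 with the mean of a gene's probes (1520 at unadjusted p under 0.05 in limma), 0 with only the 2 groups compared (1198), 0 with treated arrays of slide 1 only (1094) and 0 with those of slide 2 only (1519). Leaving out 1 array gave 0 to 1 (0 without laser replicate 3, bur replicates 1, 2, 3 or 4, or control replicate 3). Fewer samples enter the fits on 2 groups, on 1 treated slide or without 1 array. The other settings use all 12 arrays, and the cause of their counts was not tested.

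Sost kept its direction, but lost its call against control in several settings. For laser it was -0.37 with normexp, -0.48 in limma on the authors' deposited table of normalized values (adjusted p = 0.0889, against 0.0316 for the same difference in the authors' own deposited comparison), -0.80 without a filter on dim probes, -0.80 with the slide block and -0.62 with treated arrays of slide 1 only. Without 1 array it was -0.99 to -0.61, and the call was lost without any 1 laser replicate, without bur replicate 3 and without control replicate 1, 3 or 4. For bur it was 0.80 with the percentile over probes well above background on all arrays, 0.36 with normexp, 0.88 with only the 2 groups compared, 0.88 with the slide block, 0.70 with median centring, 1.11 with slide 1 only and 0.65 with slide 2 only, while it passed in the authors' own deposited comparison (0.62, adjusted p = 0.0106). Without 1 array it was 0.59 to 1.07, and the call was lost without bur replicate 1 and without control replicate 2, 3 or 4. For laser against bur it was -1.82 to -1.39 without 1 array and did not pass in any setting.

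List counts were 0 in each comparison with an estimated correlation. For laser against bur, 1 list passed with the percentile over probes well above background on all arrays, 2 with probes well above background on all arrays, 1 with the slide block, 1 with slide 1 only, 1 with only the 2 groups compared and slide as a block, and 2 to 9 without 1 array (9 without laser replicate 1 or bur replicate 3, 2 without laser replicate 4, bur replicate 1 or bur replicate 4). Chemokines lost the call without laser replicate 3 or 4 or bur replicate 1, osteoblast genes without laser replicate 1 or 4 or bur replicate 2, 3 or 4, and interferon-stimulated genes without laser replicate 1 or bur replicate 1 or 4. The correlation of responses moved to 0.853 with the controls split.

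Equal replicate numbers were not taken to pair the samples, since the labels name no shared animal and same-numbered arrays did not all deviate together. The deviations of same-numbered laser and bur arrays, which also shared a slide, correlated at 0.573, 0.045, 0.524 and 0.401 for numbers 1 to 4. With control arrays, which share no slide with them, the correlations were 0.386, 0.085, 0.136 and 0.107 for laser and 0.263, 0.094, 0.097 and 0.197 for bur. With 3 of 4 laser and 3 of 4 bur arrays correlating best with their own number, a hint of pairing or of slide remains. With the replicate block 12544, 12915 and 1 genes passed. The number of arrays and the signal over background limit what can pass.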

Other observations

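The gene family was picked after it appeared among the leading rises, and its tests were chosen before their results were seen. Olfactory and vomeronasal receptor genes, whose products detect odours and pheromones, were higher against control among the genes kept by the filter on dim probes. Of 199 kept members 66.3% were higher and 2.0% lower after laser, and 62.3% higher and 2.5% lower after bur. Of genes of like mean signal 30.7% and 32.9% were higher, and of all genes 32.2% and 32.7%. Probes were well above background on all control arrays for 34.7% of members, 53.9% of genes of like mean signal and 83.7% of all genes.

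The filter could itself favour a rise, since a gene dim on the control arrays is kept only when bright on treated ones. Among kept genes the family's median lay above that of genes of like mean signal by 1.0 (SD 0.18 over 4 arrays) for laser and by 0.83 (SD 0.33) for bur. Without the filter, over 1354 members, it lay above by only 0.018 (SD 0.012) and 0.0048 (SD 0.044), where most members are near background. Among the 63 members well above background on all arrays it lay above by 0.79 (SD 0.25) and 0.72 (SD 0.39), beyond 2 SD for laser only. An offset was expected to leave the family level with genes of like mean signal, which the kept genes contradict. That expectation took the filter to act alike on both sets, but more of the family is dim on the control arrays, so the excess among kept genes cannot decide about an offset. The filter thus stays open as the source of the family's rise, as do a signal-dependent offset of the control arrays and slide and scan, and no biological explanation was tested.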
